A study of Homo sapiens with 6 samples.

How the data were processed

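RNA recovered with an antibody against AGO2, the Argonaute protein that holds microRNAs on their target transcripts, was measured on Affymetrix gene arrays. The cells were PC3, an androgen-independent prostate cancer line, transfected with a miR-205 mimic (3 arrays) or a negative control mimic (3 arrays). The series design calls the 3 samples of each group biological replicates. All 6 arrays were AGO2 immunoprecipitates, and no array of input RNA was analysed here.

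The deposited values were log2 intensities from RMA in Affymetrix Expression Console 1.1.2, per the submitters' processing notes. They were used without further normalization. The table held 33297 probe sets, of which 21214 were in the probe annotation given for the platform. Of these, 19460 carried 1 gene symbol and 1754 carried several, and genes were named from the first kind only. A further 4203 unlisted probe sets were numbered below the lowest listed one and 7880 lay among or above the listed ones. Control probe sets could not be identified from the tables. The Entrez numbers of 19429 single-gene probe sets were found in the reference gene table, and 0 symbols needed an update. For the 769 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was taken, which left 18417 genes. No column of values was left unused.

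Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), two-sided, with Benjamini-Hochberg adjustment over the 18417 genes and a threshold of 0.05. Adjusted p-values of genes are from this limma fit. A second count took genes with an unadjusted p under 0.01 and a change of at least 1.5-fold. Gene lists were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 29 lists that had at least 5 measured genes. Camera with an estimated correlation and fry were run as alternatives. For each list, the mean of its genes minus the mean of all other genes was also taken per array and compared between groups by an exact permutation test, whose smallest p with 3 against 3 arrays is 0.1.

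The groups, the tests of genes and gene lists, the 30 gene lists, the rule for named genes and the alternatives named below were fixed before the data were examined. Added afterwards were 1 list of immediate-early and NF-kappa-B response genes, 1 alternative that removed the trend of change with signal level, and those tests of explanations that the closing part names as chosen later. The rule named, among genes past the threshold whose groups did not overlap, the 15 with the largest rise and the 10 with the largest fall, up to 4 genes per list with the smallest p, and a few genes whatever their values. Symbols of uncharacterised loci, open reading frames, FAM families, pseudogenes, olfactory receptors, keratin-associated proteins, microRNAs, small nucleolar and Cajal body RNAs, and RNU, RNY, RN5S and RN7S RNAs were kept out of the first part of the rule but stayed in the counts. A few other genes, chosen after their values were seen, are marked as such. A planned test of miR-205 seed matches in the untranslated regions was not run, since no transcript sequence was at hand.

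Alternatives covered other normalizations, filters on dim genes, other summaries of probe sets, other variance models, array weights, the replicate number as a block, and leaving out each array in turn. The number of arrays limits the precision of each value. The steps were tested on data simulated for this comparison over 18417 genes in 10 runs with 200 changed genes. At a true 1.25-fold change 19.8% of changed genes were recovered, at 1.5-fold 84.4%, at 2-fold 98.6% and at 3-fold 99.8%, while 4.48% of calls were false. A list of 24 genes lowered by 0.4 on the log2 scale was lower at an unadjusted camera p under 0.05 in 100% of runs. Of unchanged lists, 3.4% had an unadjusted camera p under 0.05. Lists of the real comparison were called on the adjusted p instead, a stricter rule. In these runs genes varied independently, lists were drawn at random, and fewer genes changed than were called in the real comparison. These rates therefore need not hold for real lists, whose genes can vary together.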

Results

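RNA bound by AGO2 was profiled in PC3 prostate cancer cells that had received a miR-205 mimic (n = 3 arrays) or a negative control mimic (n = 3 arrays). The stated aim of the series was to find transcripts targeted by miR-205. Medians of the log2 values lay between 6.82 and 6.86 over the 6 arrays. Differences between arrays of different groups had an SD of 0.275 to 0.339 over genes, against 0.131 to 0.146 among miR-205 arrays and 0.155 to 0.218 among control arrays. The first principal component held 69.5% of the variance and separated the groups. The second held 13.1% and set negative control replicate 2 (-0.875) apart from the other arrays.

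With the miR-205 mimic, some epithelial genes and some cytokine and immediate-early genes were higher in the AGO2 immunoprecipitate, and many genes reported elsewhere as miR-205 targets were lower. The cytokine and immediate-early genes were also raised in 1 control array, negative control replicate 2, above the other control arrays. CDH1, which encodes E-cadherin, rose by 1.91 ± 0.06 (log2 difference ± SE, n = 3 per group, adjusted p = 2.34e-06). EPCAM, an epithelial adhesion molecule, rose by 2.29 ± 0.10 (adjusted p = 6.7e-06), and FGFBP1, a carrier of fibroblast growth factors, by 1.96 ± 0.08 (adjusted p = 6.7e-06). The small GTPase gene ARL14 rose by 2.37 ± 0.14 (adjusted p = 2.32e-05), from a dim control mean of 5.34. The genes that fell most were RAB15, a GTPase of endosomal recycling, with -1.91 ± 0.06, and CHN1, a GTPase-activating protein for Rac, with -1.83 ± 0.06, both at an adjusted p of 2.34e-06.

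Other large falls were in NT5E (-1.72), which encodes the ectonucleotidase CD73, RASSF3 (-1.69), the transcription factor gene GLIS3 (-1.68), LBR (-1.63), the lamin B receptor, and BICC1 (-1.63), an RNA-binding protein. GXYLT1 (-1.57), JADE3 (-1.54) and PRKCH (-1.51), a protein kinase C isoform, completed the 10 largest, with adjusted p of 2.54e-05 or less for each. Among genes past the threshold whose groups did not overlap, the largest rises were in the vasoconstrictor gene EDN1 (3.26, adjusted p = 0.0398) and the neutrophil chemokine CXCL8 (3.01, adjusted p = 0.032). The orphan nuclear receptor genes NR4A2 (2.60) and NR4A1 (2.59), the chemokine genes CCL20 (2.56), CXCL2 (2.33, adjusted p = 0.0423) and CXCL1 (2.19, adjusted p = 0.0451), the transcription factor genes EGR1 (2.40) and FOSB (1.66), ZFP36 (2.10), which binds AU-rich elements, and the variant U1 RNA gene RNVU1-3 (1.62) also rose. The control means of CCL20 (5.66), RNVU1-3 (5.27) and ARL14 lay under 6.04, the 95th percentile of olfactory receptor genes, so the sizes of these rises are less certain than their direction. In negative control replicate 2 the cytokine and immediate-early members of this set stood well above the other control arrays. RNVU1-3 did so too, at 6.21 in that array, against 4.75 and 4.85 in the other control arrays and 6.89 with miR-205. Without that array, EDN1 was higher by 4.70 and CXCL8 by 4.27, with CXCL2 at 3.38, CCL20 at 3.30, CXCL1 at 3.20 and ZFP36 at 2.89. Leaving out any 1 of the other 5 arrays instead ended the calls of EDN1, CXCL8, CXCL2, CXCL1 and ZFP36 (adjusted p = 0.0568 to 0.158), and so did a robust variance with a trend (0.133 to 0.202). Testing all probe sets ended these calls too, except that of ZFP36. That variance also ended the calls of CCL20 (0.0717) and RNVU1-3 (0.0612), and repeated quantile normalization that of CXCL1 (0.052).

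Of 18417 genes, 4906 (26.6%) changed at an adjusted p under 0.05 by limma, 2320 upward and 2586 downward. Their median absolute log2 change was 0.363. At least 2-fold changes that passed numbered 97 upward and 70 downward. Under the second criterion (unadjusted p under 0.01 and 1.5-fold), 403 genes rose and 460 fell, 863 in all. At an unadjusted p under 0.01 alone there were 4554 genes, where chance would give 184. The arrays of the groups did not overlap for 7766 genes (42.2%), where chance gives 10%.

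**Figure D1:**
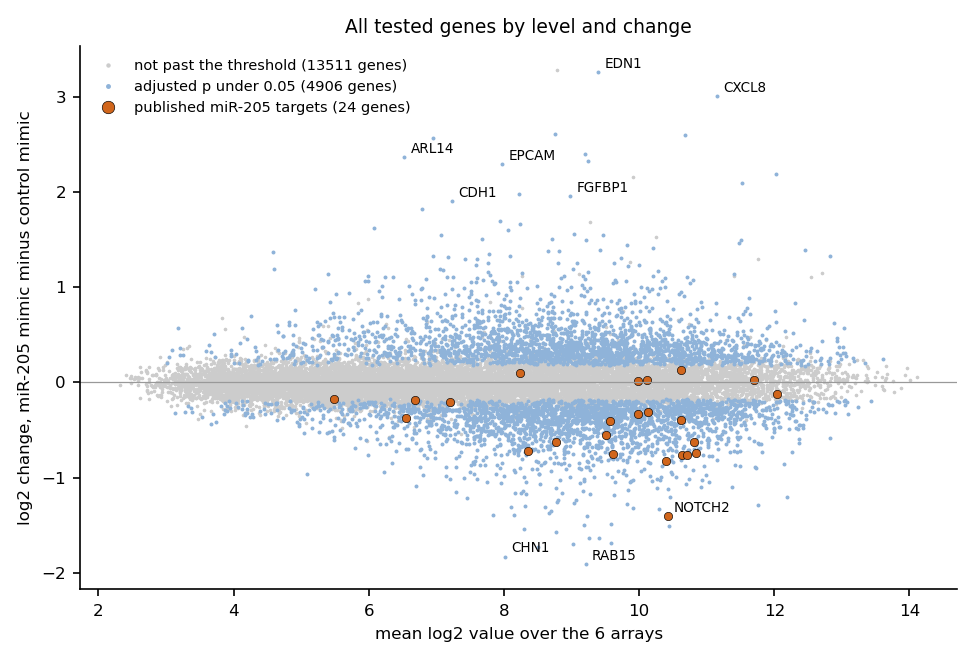
Log2 change with the miR-205 mimic (vertical axis) against the mean log2 value over the 6 arrays (horizontal axis), 1 point per gene. Genes past an adjusted p of 0.05 are blue, others grey, and the 24 measured published miR-205 targets are orange, of which 15 fell and 0 rose.

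Among genes reported in the literature as direct miR-205 targets, 24 of 27 were measured, and 15 fell, 0 rose and 9 did not pass. Adjusted over the list alone, 17 fell and 0 rose. The receptor gene NOTCH2 fell by 1.40 (adjusted p = 1.73e-05). ZEB1, a repressor of epithelial genes, had a log2 change of -0.82 (9.98 ± 0.10 against 10.8 ± 0.03, mean ± SD, n = 3 each, adjusted p = 9.43e-05). The integrin gene ITGA5 (-0.76), the Mediator subunit MED1 (-0.76), TP53INP1 (-0.75) and the laminin chain LAMC1 (-0.74) also fell. ZEB2 (-0.18, adjusted p = 0.119), ERBB3 (-0.21, adjusted p = 0.0881) and VEGFA (0.13, adjusted p = 0.318) did not pass. ZEB2 was dim, with both group means under 6.04, the 95th percentile of olfactory receptor genes, so a fall of ZEB2 could be missed. As a set the targets had a median log2 change of -0.38 and were lower than other genes (camera adjusted p = 4.2e-07, adjusted p = 0.144 with an estimated correlation). Per array, the targets lay 1.55 ± 0.02 above the other genes with miR-205 and 1.96 ± 0.02 with the control (mean ± SD, n = 3 each). The difference was -0.41, with an exact permutation p of 0.1, the smallest that 3 against 3 arrays can give. Lists that camera did not call, such as the miR-17 family targets (-0.07) and apoptosis regulators (-0.06), had the same exact p. It therefore does not set the miR-205 targets apart. Exchanged labels of the 2 groups would turn every sign, and no probe set used here reads the mimic itself. With no input arrays analysed here, a change in AGO2 binding and a change in transcript abundance give the same reading.

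**Figure D2:**
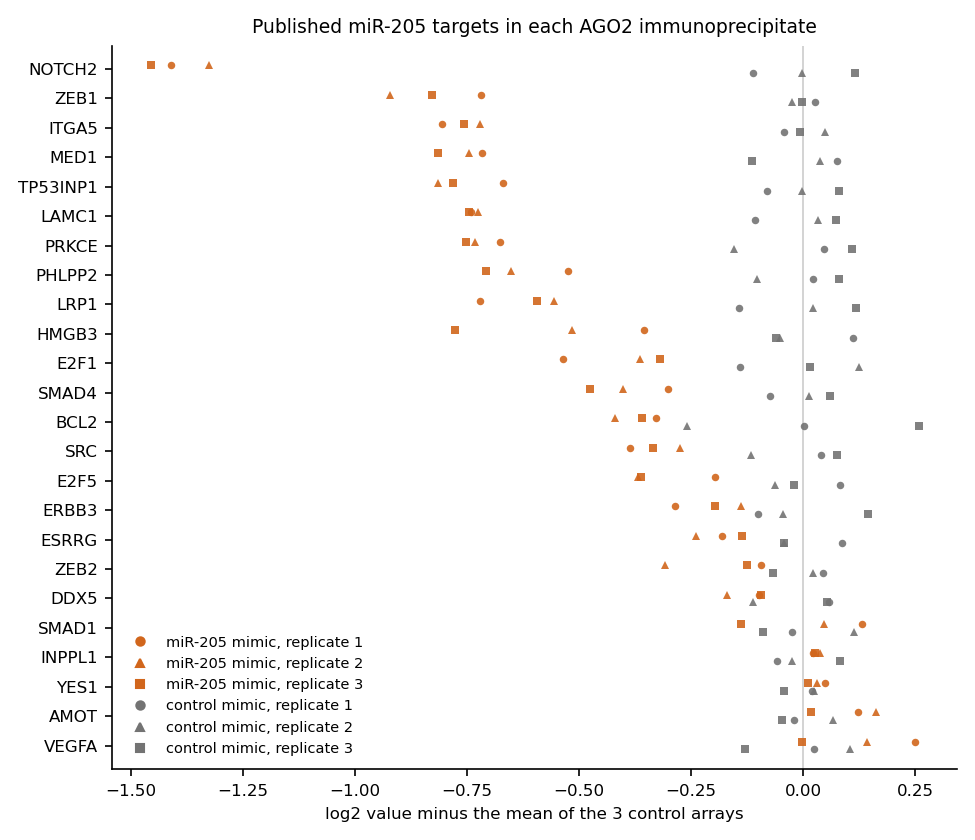
Log2 value of each of the 24 measured published miR-205 targets in each array, minus the mean of the 3 control arrays (horizontal axis), with miR-205 arrays in orange, control arrays in grey and 1 symbol shape per replicate number. NOTCH2 lies lowest with a mean change of -1.40, and VEGFA highest with 0.13.

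Targets of other microRNAs were compared in the same way. Of 18 measured let-7 targets, 5 fell and 0 rose (7 and 1 without negative control replicate 2), among them the cyclin-dependent kinase gene CDK6 (-1.14) and DICER1 (-0.42). The median was -0.13, with a camera adjusted p of 0.0187 and an adjusted p of 0.21 with an estimated correlation. Of 17 miR-21 targets, 7 fell and 1 rose (0 to 3 with 1 array left out, the most without negative control replicate 2), among them RECK (-0.96), an inhibitor of matrix metalloproteases, and MARCKS (-0.67). Their median was -0.18, with a camera adjusted p of 0.00996 and an adjusted p of 0.21 with an estimated correlation. Of 17 miR-17 family targets, 5 fell, including TGFBR2 (-0.65) and E2F1 (-0.41), and 2 rose (1 to 2 with 1 array left out), including TXNIP (0.92; adjusted p = 0.0501 with a robust variance with a trend), with a camera adjusted p of 0.71.

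Epithelial genes that passed were higher, and mesenchymal genes that passed were lower with 1 exception. Of 24 measured epithelial junction and keratin genes, 11 rose, 0 fell and 13 did not pass, with a median log2 change of 0.12 (camera adjusted p = 1.72e-05, adjusted p = 0.144 with an estimated correlation). Besides CDH1 and EPCAM, the tight junction gene CLDN1 (1.09) and the keratin gene KRT8 (0.89) rose. Of 30 mesenchymal genes, 13 fell and 1 rose, with a median of -0.19 (camera adjusted p = 0.000564, adjusted p = 0.274 with an estimated correlation). MMP14, a membrane-bound metalloprotease, fell by 0.99, next to ZEB1, ITGA5 and LAMC1, which also stand in the list of miR-205 targets. The gene that rose was THBS1, a thrombospondin (0.72), named after its values were seen, and 0 mesenchymal genes were higher when any 1 array other than miR-205 replicate 1 or negative control replicate 2 was left out. Without negative control replicate 2, 4 mesenchymal genes rose and 13 fell, with a camera adjusted p of 0.0395. The mean of the mesenchymal list over that of other genes was 2.20 in that array, 2.00 and 2.01 in the other control arrays and 1.92 ± 0.02 (SD, n = 3) with miR-205. The matricellular gene CCN1, chosen after its values were seen, stood at 13.1 in that array, against 11.4 in the other control arrays and 13.1 ± 0.09 (SD, n = 3) with miR-205.

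Of 34 extracellular matrix and integrin genes, 18 fell and 3 rose, with a median of -0.20 (camera adjusted p = 0.000446, adjusted p = 0.395 with an estimated correlation). ITGA5 and LAMC1, named above among the miR-205 targets and mesenchymal genes, had the smallest limma p-values of this list too. The integrin genes ITGB8 (-0.80) and ITGB5 (-0.64) fell, as did NID1 (-0.74), a basement membrane linker chosen after its values were seen. ITGB4, a subunit of the laminin receptor of hemidesmosomes, rose by 0.77. Of 30 interferon-stimulated genes, 16 rose (10 without negative control replicate 3) and 0 fell, with a median of 0.25 (camera adjusted p = 1.65e-06, adjusted p = 0.21 with an estimated correlation). IFIH1, a sensor of double-stranded RNA, rose by 1.11 from a dim control mean of 5.69, OAS1 by 0.62 and IFIT1 by 0.50. The interferon regulator IRF1, chosen after its values were seen, stood at 11.1 in negative control replicate 2, against 8.50 and 8.89 in the other control arrays.

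**Figure D3:**
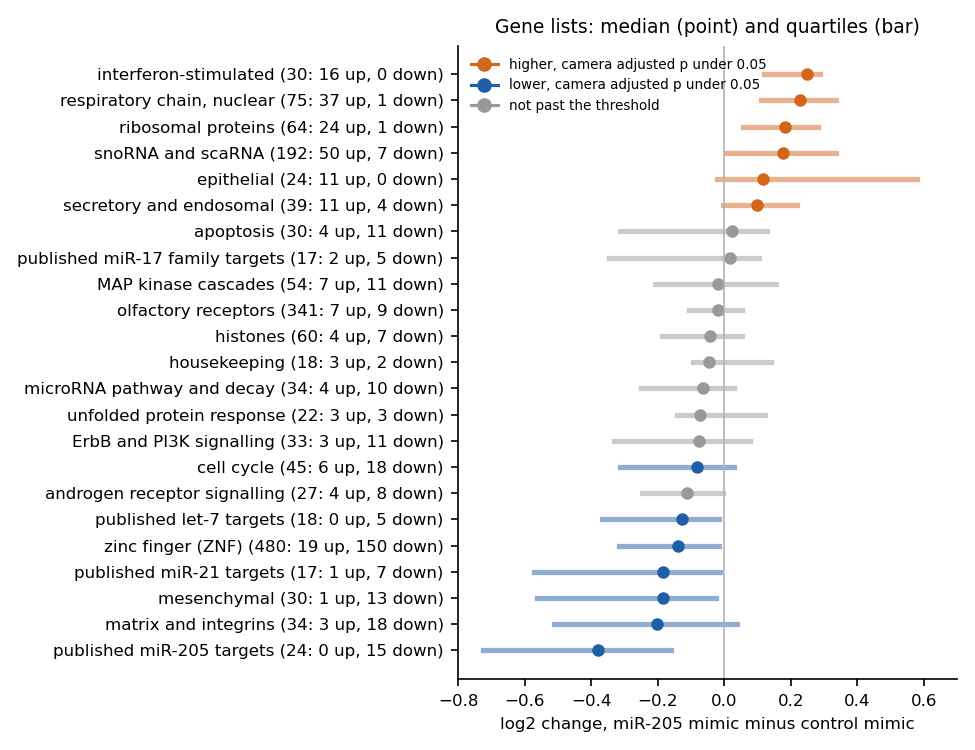
Median (point) and quartiles (bar) of the log2 change over the measured genes of each tested fixed list other than the cell type markers, with the number of genes that rose and fell. Lists higher by camera are orange and lists lower are blue, with the published miR-205 targets lowest at a median of -0.38.

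Respiratory chain and ribosomal protein genes that passed were nearly all higher. Of 75 nuclear-encoded respiratory chain genes, 37 rose (22 to 43 with 1 array left out) and 1 fell, with a median of 0.23 (camera adjusted p = 6.77e-12, adjusted p = 0.274 with an estimated correlation). NDUFB5 (1.41) and COX7B (1.39) rose most clearly. Of 64 ribosomal protein genes, 24 rose (12 to 27 with 1 array left out) and 1 fell, RPS23 by 0.78 and RPL37A by 0.68 (camera adjusted p = 5.89e-08, adjusted p = 0.388 with an estimated correlation). Of 192 small nucleolar and Cajal body RNAs, 50 rose (28 to 74 with 1 array left out) and 7 fell, among them SNORD28 (0.75) and SNORA24 (0.67), with a camera adjusted p of 7.02e-07 and an adjusted p of 0.346 with an estimated correlation. Of 480 zinc finger genes, 150 fell and 19 rose, with a median of -0.14. ZNF138 fell by 1.04 and ZNF92 by 0.88, and ZNF204P rose by 1.38 (camera adjusted p = 7.02e-07, adjusted p = 0.344 with an estimated correlation). Of 39 secretory and endosomal trafficking genes, 11 rose (7 to 11 with 1 array left out) and 4 fell, the latter including RAB14 (-0.78), RAB11FIP1 (-0.65) and RAB8A (-0.42), while ARF3 rose by 0.34 (camera adjusted p = 0.0209, adjusted p = 0.21 with an estimated correlation). Negative control replicate 2 lay between the other control arrays and the miR-205 arrays for 4 of these lists. Relative to other genes, its mean was -1.53 for the small nucleolar and Cajal body RNAs, against -1.70 and -1.71 in the other control arrays and -1.43 with miR-205. The respiratory chain mean was 2.07 there, against 1.99 and 1.94 in the other control arrays and 2.27 with miR-205, and the ribosomal protein mean was 3.11, against 3.05 and 2.99, and 3.25 with miR-205. The zinc finger mean was -0.02, against 0.05 and 0.06, and -0.13 with miR-205.

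Signalling, proliferation and microRNA pathway genes were mixed. Of 45 cell cycle genes, 18 fell, including CDK6, MKI67 (-0.77) and BUB1 (-0.69), and 6 rose (camera adjusted p = 0.0289, adjusted p = 0.4 with an estimated correlation, and 0.0654 by camera without negative control replicate 2). Of 27 androgen receptor coregulator and response genes, 8 fell, including the acetyltransferase gene KAT2B (-1.02) and HOXB13 (-0.73), and 4 rose (1 to 3 with 1 array left out), including FKBP4 (0.75), with a camera adjusted p of 0.0566, and 0.0492 without negative control replicate 2. Of 54 MAP kinase genes, 11 fell (7 to 13 with 1 array left out), including MAP4K4 (-0.90) and NLK (-0.94), and 7 rose (11 without negative control replicate 2), including RRAS2 (0.69), with a camera adjusted p of 0.853. Of 33 ErbB and PI3K genes, 11 fell, including EGFR (-0.50), and 3 rose (camera adjusted p = 0.162). Of 34 microRNA pathway and RNA decay genes, 10 fell (6 to 11 with 1 array left out), including DCP2 (-0.75), AGO2 (-0.73) and TNRC6B (-0.67), and 4 rose, including MOV10 (0.53), with a camera adjusted p of 0.18.

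Of 30 apoptosis regulators, 11 fell (7 to 12 with 1 array left out), including TNFRSF10B (-0.92), and 4 rose (camera adjusted p = 0.71). Of 22 unfolded protein response genes, 3 fell (1 to 4 with 1 array left out), including SEL1L (-0.83), and 3 rose (5 without negative control replicate 2), including ATF3 (1.30; adjusted p = 0.0773 with a robust variance with a trend). ATF3 stood at 7.58 in negative control replicate 2, against 6.60 and 6.16 in the other control arrays. The list had a camera adjusted p of 0.869. Of 60 histone genes, 7 fell (2 to 12 with 1 array left out, the most without negative control replicate 2) and 4 rose (2 to 5) (camera adjusted p = 0.71). Of 18 housekeeping genes, 3 rose, including B2M (0.75), and 2 fell (0 to 2 with 1 array left out, camera adjusted p = 0.859). Among 341 olfactory receptor genes, 7 rose (4 to 8 with 1 array left out) and 9 fell (2 to 16, the most without negative control replicate 2, camera adjusted p = 0.869). No list of cell type markers passed by camera, while fry, which sets a list against no other genes, called the basal prostate markers higher (adjusted p = 0.0136). For luminal prostate, basal prostate, neuroendocrine, fibroblast, leukocyte and liver markers, camera adjusted p-values were 0.71, 0.371, 0.859, 0.838, 0.486 and 0.869. Of 8 liver markers, 1 had a mean above 6.04, the 95th percentile of olfactory receptor genes, as did 3 of 9 leukocyte and 6 of 7 basal prostate markers. The same held for 4 of 6 luminal prostate, 3 of 8 neuroendocrine and 5 of 10 fibroblast markers. No gene of the mitochondrial genome was among the genes named here.

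Over the 29 lists tested, camera called 13, of which 6 were higher and 7 lower. With an estimated correlation 0 lists passed (6 had an unadjusted p under 0.05), and fry called 16.

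**Figure D4:**
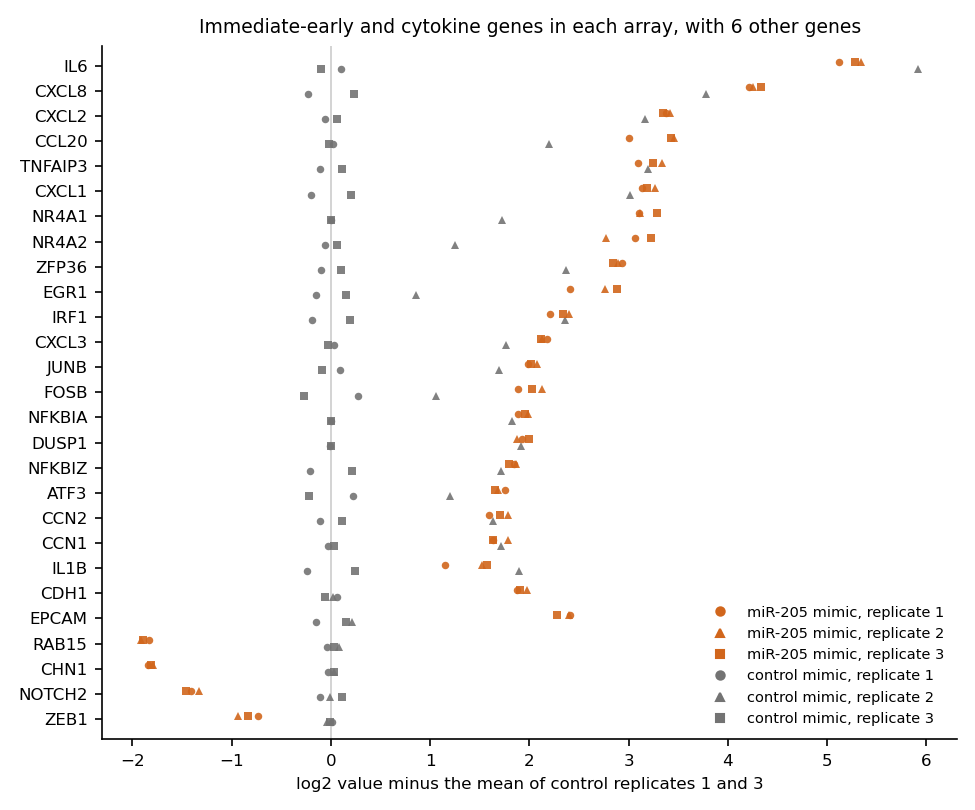
Log2 value in each array minus the mean of negative control replicates 1 and 3 (horizontal axis) for 21 immediate-early and cytokine genes at least 2-fold higher with miR-205 than in those arrays, and for 6 other genes below. Negative control replicate 2 (grey triangles) lies near the miR-205 arrays for most of the 21 genes and at the level of the other control arrays for CDH1, EPCAM, RAB15, CHN1, NOTCH2 and ZEB1.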

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

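The comparison with other microRNAs' target lists, both tests on negative control replicate 2 and the reading of the estimated correlation as a test of co-varying genes were tests chosen only after results were seen, and so was the removal of the trend with signal level as a setting.

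Probe sets without a single gene name also differed between the groups. Of 9634 tested, 603 were higher and 319 lower with miR-205 by limma, 34 of them at least 2-fold higher and 12 at least 2-fold lower, with extremes of 2.54 and -1.65.

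Published miR-205 targets were lower in the AGO2 immunoprecipitate of miR-205 cells. The test had been planned on the opposite expectation, that transcripts bound by miR-205 would be recovered with AGO2. A loss of target transcripts under the mimic is a candidate explanation that the arrays leave untested. A trend of change with signal level is argued against, since the list stayed lower once the trend was removed (camera adjusted p = 2.509e-07, median -0.37 against -0.38). The median was -0.35 for the 22 measured miR-205 targets that were not in the let-7, miR-17 family or miR-21 lists. For the 47 genes of those 3 lists it was -0.07. The difference was -0.2768 (permutation p = 0.0292, over genes, which are not independent replicates). This argues against an equal fall of targets of any microRNA, while a smaller shared fall stays open. By camera, let-7 (median -0.13, adjusted p = 0.0187) and miR-21 targets (-0.18, adjusted p = 0.00996) were lower too. The miR-17 family targets were not (median 0.02, adjusted p = 0.71). RNA carried over in proportion to its abundance stays open, because housekeeping transcripts lay at percentile 99.46 of all genes and no input arrays were analysed here.

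Negative control replicate 2 carried many cytokine and immediate-early transcripts near the miR-205 level, while others lay between the levels. EGR1 stood at 8.57 there, against 7.57 and 7.87 in the other control arrays and 10.4 with miR-205. NR4A2 stood at 8.29, against 6.98 and 7.10, and 10.1 with miR-205. For 21 cytokine and immediate-early genes, the miR-205 arrays were at least 2-fold above control replicates 1 and 3. On the log2 scale, 19 of these genes lay more than midway towards the miR-205 level in negative control replicate 2. From 0 (the other control arrays) to 1 (miR-205), the median position of the 21 was 0.936 on the log2 scale. On a linear scale it was 0.845, with quartiles of 0.573 and 0.974. A wrong label is argued against, because the 15 published targets that fell in a fit without that array had a median position of 0.003785 there on the log2 scale, and all 24 lay 1.95 above other genes in it, against 1.95 and 1.98 in the other control arrays. Admixed RNA of miR-205 cells is argued against too, since the 11 epithelial genes that rose in that fit had a median position of 0.03593 (linear, quartile range 0.0621). A response to transfection or handling that varied between cultures may underlie this part of the difference, and the labels give no batch with which to test it.

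Of respiratory chain genes 37 of 75 were higher with miR-205, of ribosomal protein genes 24 of 64, while 150 of 480 zinc finger genes were lower. A trend of change with signal level is argued against, since 3 of these 3 lists stayed past the threshold in the same direction once it was removed. Whether genes of a list varying together between arrays account for the small p-values cannot be told from the estimated correlation. In that setting 0 of the 3 lists passed, but so did 0 of all 29, the published targets included. The epithelial list lost its call as well (camera adjusted p = 0.144), with an estimate of -0.000941 where 0.01 was preset. At an unadjusted camera p under 0.05 that setting kept 6 lists, but not these (respiratory chain 0.0688, ribosomal protein 0.161, zinc finger 0.107). The estimates for these were 0.194, 0.288 and 0.0776. No biological explanation was tested for them.

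The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 4906 genes against at most 0 in another split, 863 against 10 under the second criterion, 13 gene lists against 8, and a camera adjusted p for the published targets of 4.2e-07 against 0.005098. Every other split put arrays of both groups on each side, so a group difference widens its spread and holds gene calls down. The low gene counts of those splits are therefore no measure of noise. Part of the group difference also stays in the means of those splits. Their list calls and camera p-values for the published targets are thus no measure of noise either.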

How the results depend on the processing

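The trend-removed setting was added to the tests after the data were seen, and the planned seed-match test was not run for lack of transcript sequence. The number of changed genes ranged from 3365 (without miR-205 replicate 2) to 5549 (without negative control replicate 2) against 4906, with 44.9% to 50.8% of them upward. Without negative control replicate 2, 4507 of the 4906 changed in the same direction. The published targets stayed lower with camera adjusted p between 1.24e-08 and 7.308e-05 over 17 settings that kept the preset correlation. With the correlation estimated, their adjusted p was 0.144 and 0 gene lists passed (6 at an unadjusted p under 0.05), while fry called 16. The estimate gave up to 0.288 for a list where 0.01 was preset, and 0.032 for the published targets. The epithelial (-0.000941), let-7 (-0.0215), miR-21 (-0.0582) and trafficking (-0.00766) lists lost their calls with estimates below 0.01. Over those 17 settings the cell cycle list lost its call in 3, the miR-21 targets and the trafficking list in 1 each (trafficking at 0.05114 without the trend), the androgen receptor list gained one in 7, and the ErbB and PI3K list in 1 (0.04595 for genes above the median level). Of 115 named genes that passed, 18 lost the call in at least 1 alternative, and 0 of 134 turned direction. Replicate numbers did not pair the arrays (correlations of deviations 0.0626, 0.0912 and 0.0103), and the replicate block gave 4627 genes. Dim signal limits 262 changed genes, whose means in both groups lay under 6.04, the 95th percentile of olfactory receptor genes.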

Other observations

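The list of immediate-early and NF-kappa-B response genes was among the tests chosen only after results were seen. Of its 35 genes, 34 were measured, and 19 rose and 0 fell with miR-205, with a median log2 change of 1.28. Without negative control replicate 2, 28 rose, 0 fell and the median was 1.77. The mean of the list over that of other genes was 2.47 to 2.57 in the miR-205 arrays, 2.25 in negative control replicate 2, and 0.739 and 0.809 in control replicates 1 and 3. The cytokine gene IL6, chosen after its values were seen, had log2 values of 10.3, 10.5 and 10.5 with miR-205, 11.1 in negative control replicate 2, and 5.28 and 5.08 in the other control arrays. Its difference of 3.28 did not pass with all arrays (adjusted p = 0.108 by limma) and was 5.25 without that array, against control values under 6.04, the 95th percentile of olfactory receptor genes, which leaves the size uncertain.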
